A study of Homo sapiens with 3 samples.

How the data were processed

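SK-Hep-1 is an established human line taken from a liver adenocarcinoma, with endothelial traits. Lines carrying a lentiviral short hairpin RNA stably were compared as 3 groups of 1 library each. The shNC group is the negative control, and the sh1089-1 and sh1089-2 groups carry different hairpins against the long noncoding RNA LINC01089. Per the labels' protocols, total RNA was taken up in Trizol, mRNA was enriched and strand-specific libraries were built. The submitters' processing notes name FastQC, StringTie and build GRCh38, without versions. The aligner, the trimming and the annotation release are not given in the sources used here, nor is it given whether counting used the strand.

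The deposited table gives FPKM, fragments scaled by gene length and library size, as the authors computed them, for 22464 Ensembl gene identifiers in 3 libraries. Symbols were found for 20952 identifiers, and 1512 were left without. Of the identifiers, 22444 are in GENCODE release 29 on GRCh38, which gave the gene types and all coordinates below. The listed genes comprise 16858 protein-coding genes, 4338 pseudogenes and 27 lincRNA genes. LINC01089 itself was not analysed here, so the depth of the knockdown is not reported, and no library label was checked against the target.

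Depth was worked out from the values. In the low genes, each FPKM is a whole number of reads divided by the gene length and the library total, so the step between values gives both. For 19219 genes with a value above 0 a whole length was searched that made all 3 values whole reads, within the rounding of the deposited decimals, and it was found for 100% of them. The length equalled the summed exon length in GENCODE 29 for 61.9% of genes and lay within 5% of it for 93.4%. That match is partly built in. Where several lengths fitted, the one nearest to GENCODE 29 was taken, and the library totals were also derived with GENCODE 29 lengths. On simulated values the true reads came back exactly in 99.9% of 2000 genes, and 0 of 1209 genes with scrambled libraries passed. The scrambled check left out genes with few reads, for which a fitting length is easier to find. The library totals are 10698480 reads for shNC, 9528312 for sh1089-1 and 8359832 for sh1089-2, of which 95.3%, 95.0% and 94.8% lie in listed genes. The recovered reads served for depth, for 95% Clopper-Pearson intervals of ratios and for a filter. No count test was run on them. A count of 0 allows up to 0.280, 0.315 and 0.359 RPM in the 3 libraries (3 reads of the total). Reads carry no molecular identifiers, so intervals and floors cover counting error only.

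With 1 library per group there is no spread between replicates, and no p-value is given for a comparison of 2 libraries. The limma fit among the alternatives takes the hairpins as replicates against a single control library, and its p-values are not given either. Genes were named by size: a difference of at least 1 in log2(FPKM + 1), which is 2-fold, among 11198 genes with a mean FPKM of at least 1 over the 3 libraries. The pseudocount of 1 understates the change of low genes. Fold values printed for single genes are ratios of FPKM without a pseudocount, while every threshold of 1.5-fold, 2-fold or 3-fold applies to log2(FPKM + 1). Because 244 of the 11198 genes are short noncoding RNAs, which rest on few reads, the counts were repeated over 10122 protein-coding genes with at least 100 recovered reads in all. That filter was chosen after the data were examined.

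Both hairpins were set against the same shNC library. The overlap, the correlation and the covariance of their differences were therefore set beside 100 simulations of 3 unchanged libraries, with noise drawn from the difference between the hairpin libraries in genes of like expression. The overlap of independent lists (n1 × n2 / N) stands beside them. On simulated reads with genes changed by known folds in both hairpins, the 2-fold rule recovered 0% of 50 genes at 1.5-fold, 71.7% of 46 at 3-fold, 90.7% of 43 at 4-fold and 100% of 45 at 6-fold. It called 49 of 11046 unchanged genes in both hairpins, and 0 of 9896 under the filter on type and reads. These reads carried counting error and an assumed spread of 0.1 (natural log) per library. With noise from the hairpin libraries, the unchanged simulations gave more such genes, 93.3 and 4.41 on average.

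The design, the alternatives, the naming rule and 37 gene lists were fixed before the data were examined. For each list the median difference was given with a 95% order-statistic interval over its members. Its percentile was taken among 10000 random lists of the same size, matched in 20 bins of mean expression. A list is called higher or lower where the percentile lies above 97.5 or below 2.5 in both hairpins. Of 200 random lists drawn from the measured differences of sh1089-1 alone, 3.5% lay outside those bounds. Drawn from the same genes as the comparison lists, they check the calculation only. They do not give the rate of false calls for genes that move together. These percentiles describe the 3 libraries and are not tests across replicates. A member counts as higher or lower where both hairpins differ from shNC by at least 1.5-fold in log2(FPKM + 1) in the same direction, so low genes can pass 1.5-fold as a plain ratio and not count.

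The naming rule took the proposed LINC01089 partners, the 12 higher and 12 lower genes with the largest smaller difference of the 2 hairpins, the 5 genes per hairpin and direction where the other hairpin lay within 0.25 (log2) of shNC, genes past 2-fold in opposite directions, up to 4 members per list, and the measured transcription factors of the epithelial-mesenchymal transition. Since most of the 24 genes of the second part were short RNAs with few reads, the same ranking was repeated over the protein-coding genes with at least 100 reads. That ranking lies outside the rule, and not every gene taken by the rule is printed. Also outside it, and chosen after their values were seen, are the list members IL11, TNFAIP3, SESN1, MDM2 and FOSL1, the single genes MYBL2, PLAT, TXNIP, KRT81, GAGE12G, EIF3C and EIF3CL where they are set between libraries, and those said to be so chosen in the closing section. Members that counted as higher or lower, also by plain ratios, were named to fill out the counts, HMGCS1, SQLE and SC5D were named by sign, and the neighbours of LINC01089 were taken by position.

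The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, rescaling so that all libraries had the same sum (TPM), scaling so that the median gene had ratio 1, thresholds of 1.5-fold and 3-fold, member counts from plain ratios (added after the data were examined), and a limma-trend fit that took the hairpins as 2 replicates, with 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. Families of at least 8 protein-coding genes with a shared symbol stem were scanned without a prior list. Trends with GC content and gene length were removed by lowess. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1.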

Results

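Gene expression was measured by RNA sequencing in SK-Hep-1 cells that stably carried a control hairpin (shNC) or 1 of 2 hairpins against LINC01089 (sh1089-1 and sh1089-2), to ask which genes depend on that long noncoding RNA. Each group is 1 library, so the differences have no replicate check. The libraries held 10698480 reads (shNC), 9528312 (sh1089-1) and 8359832 (sh1089-2). At 1 FPKM or more, 11361, 11046 and 11195 genes were detected. Mitochondrial genes took 5.24%, 4.69% and 5.10% of the reads.

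LINC01089 is annotated on chromosome 12 from 121795267 to 121803906, on the minus strand of GRCh38, as a lincRNA gene. Its level was not analysed here. The 4 protein-coding neighbours above 1 FPKM stayed within 2-fold of shNC in both hairpin libraries. RHOF, a gene on the same strand that overlaps LINC01089 (121777754 to 121803403), had 8.80 FPKM in shNC, 6.64 in sh1089-1 and 8.55 in sh1089-2. SETD1B, a histone methyltransferase gene that starts 274 bp away on the other strand, had 4.99, 4.87 and 3.84 FPKM. TMEM120B had 9.15, 8.06 and 9.15 FPKM, and ORAI1, a calcium channel gene, had 20.9, 22.7 and 20.7 FPKM. MORN3 and HPD lay below 1 FPKM in each library, on 11, 8 and 5 and on 7, 7 and 1 reads.

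The first comparison was sh1089-1 against shNC. Cell division and interferon-induced genes were higher in the knockdown library, and NRF2 target and lysosomal genes were lower. MYBL2, a transcription factor of the cell cycle, stood 3.28-fold above shNC (95% counting interval 3.04 to 3.54), and PLK1, a mitotic kinase, 3.0-fold (2.72 to 3.31). GDF15, a stress-induced secreted factor, was 4.73-fold lower (4.55 to 4.93), and EPAS1, which encodes HIF-2α, was 4.96-fold lower (4.58 to 5.37). Of 11198 genes, 154 were at least 2-fold higher and 169 at least 2-fold lower. Among the 10122 protein-coding genes with at least 100 reads the counts were 82 and 68.

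The second comparison, sh1089-2 against shNC, gave the same main groups, with lipid synthesis genes further above the control. SCD, the stearoyl-CoA desaturase, was 3.41-fold higher (3.26 to 3.56) and FASN, the fatty acid synthase, 3.53-fold (3.44 to 3.63). PLAT, which encodes tissue plasminogen activator, was 4.95-fold higher (4.61 to 5.32). GDF15 was 5.37-fold lower (5.14 to 5.62) and FTL, the ferritin light chain, 2.70-fold lower (2.67 to 2.73). Here 183 genes were at least 2-fold higher and 180 lower, and 101 and 65 among the protein-coding genes with at least 100 reads.

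Both hairpins were then considered jointly, since a gene that moves with either hairpin is less open to an effect of a single hairpin sequence. By the protein-coding ranking, the genes with the largest higher values in both were TENT5B, of a family of noncanonical poly(A) polymerases, OASL and RSAD2, both interferon-induced, NRGN, ADAMTS6, SLC27A2, a fatty acid transport gene, and the cell division genes PLK1, KIFC1, RRM2, MYBL2, TK1 and KIF18B. TENT5B (chromosome 1, 27005020 to 27012836) had 3.65, 14.3 and 13.5 FPKM in shNC, sh1089-1 and sh1089-2. OASL (chromosome 12, 121019111 to 121039242) had 16.4, 51.1 and 61.6 FPKM. PLK1 (chromosome 16, 23677656 to 23690367) had 11.3, 33.8 and 34.0 FPKM. ADAMTS6, a secreted metalloprotease gene, was 3.96-fold (3.33 to 4.73) and 3.91-fold (3.28 to 4.68) higher.

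The 12 protein-coding genes with the largest lower values were HSPA6, GDF15, PTGES, EPAS1, KRT86, HPS5, AKR1C3, IL1B, TDO2, SPP1, CCN5 and H2BC5. HSPA6 (chromosome 1, 161524540 to 161526910), a stress-inducible member of the HSP70 family, had 14.8 FPKM in shNC and 1.52 and 1.47 in the hairpin libraries. GDF15 (chromosome 19, 18374731 to 18389176) had 687, 145 and 128 FPKM. PTGES (chromosome 9, 129738331 to 129753047), a prostaglandin E synthase gene, had 71.9, 13.3 and 14.9 FPKM. EPAS1 (chromosome 2, 46293667 to 46386703) had 52.3, 10.6 and 13.7 FPKM. SPP1, which encodes osteopontin, was 2.76-fold (2.5 to 3.06) and 3.06-fold (2.75 to 3.42) lower. EPAS1 and HPS5 lie in stretches of chromosomes 2 and 11 whose 50 genes had medians of −0.27 and −0.33, and −0.30 and −0.36, in the 2 hairpins. KRT86 and AKR1C3 have close relatives in the genome that could share reads, so their values are uncertain.

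In all, 81 genes were at least 2-fold higher in both hairpins and 83 lower. The split depended on the processing: 154 higher to 103 lower after rescaling to TPM and 56 to 27 at a mean FPKM of at least 5, but 87 to 192 with no filter and 9 to 32 at 3-fold. Of the 164 genes, 86 were protein-coding, 59 were short noncoding RNAs and 77 had fewer than 100 reads over the 3 libraries. Among protein-coding genes with at least 100 reads, 50 were higher and 34 lower in both, where independent lists would share 0.818 and 0.437 genes. Simulated unchanged libraries with a shared control gave 4.41 such genes on average (0 to 9 in 100 simulations), against the 84 observed. Over all 11198 genes they gave 93.3 (67 to 119), against 164. Put another way, shNC stood apart from both other libraries in 84 of these protein-coding genes, sh1089-1 in 3 and sh1089-2 in 5. An effect of the hairpins and a peculiarity of the single shNC library give the same count.

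Across the 11198 genes the differences of the 2 hairpins had a Pearson r of 0.668 and a Spearman correlation of 0.679. Genes are not independent replicates, and the shared control alone gave 0.502 and 0.474 in the simulations. The covariance was 0.121, against 0.0607 simulated, a difference of 0.0604. In the protein-coding genes with at least 100 reads r was 0.755 against 0.498, and the covariance 0.0939 against 0.0304. The control could not be split, so part or all of the excess may come from the shared shNC library.

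**Figure D1:**
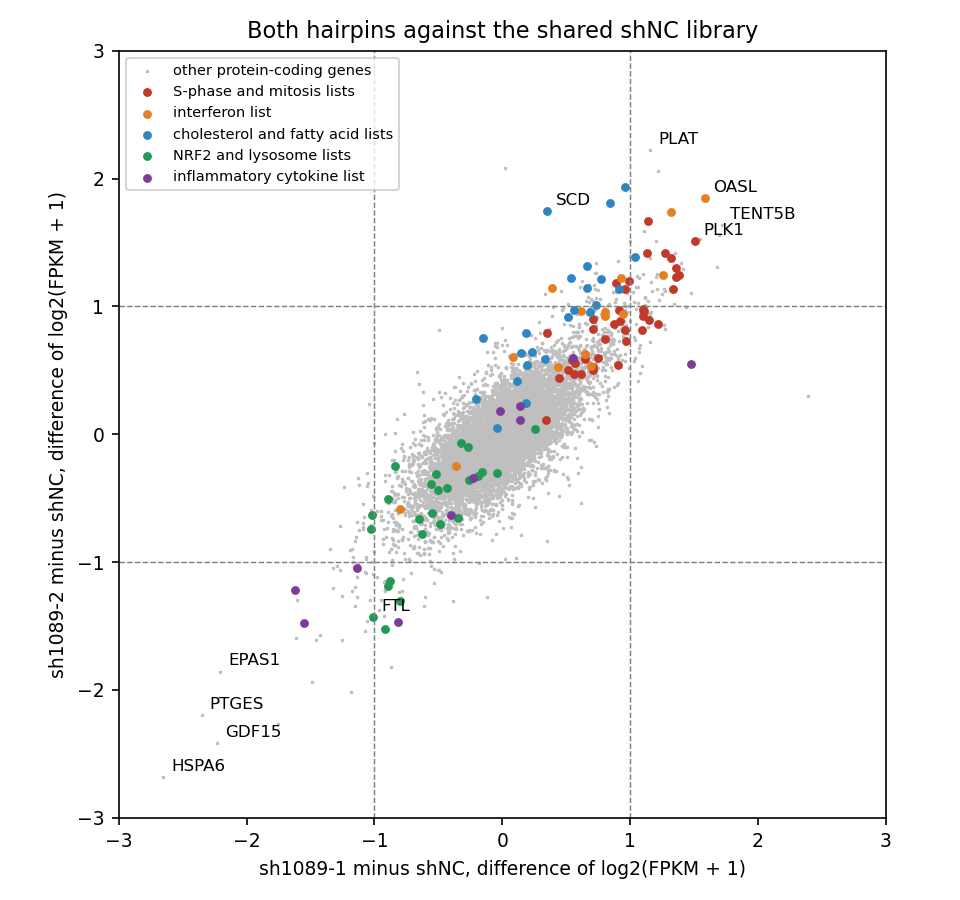
Difference of log2(FPKM + 1) from shNC in sh1089-1 (x axis) and in sh1089-2 (y axis) for protein-coding genes with at least 100 reads, with 5 sets of gene lists in colour and dashed lines at 2-fold. S-phase and mitosis genes lie in the upper right, GDF15, PTGES and EPAS1 in the lower left, and SCD lies above the 2-fold line for sh1089-2 alone, while GAGE12J (5.04 and 0.00) and GAGE12G (0.38 and 4.62) fall outside the axes.

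Genes of DNA replication and mitosis were higher in both hairpin libraries. All 20 members of the S-phase and E2F list were above shNC in both, 14 of them by at least 1.5-fold in log2(FPKM + 1), the scale of all such counts here. RRM2, the small subunit of ribonucleotide reductase, had 21.4, 54.8 and 57.2 FPKM in shNC, sh1089-1 and sh1089-2. TK1, thymidine kinase, had 56.8, 147 and 141 FPKM. MCM7 and MCM5, subunits of the replicative helicase, were 2.55-fold and 2.46-fold higher in sh1089-1, and 2.23-fold and 1.90-fold higher in sh1089-2. The mitosis list had 19 measured members, all above shNC in both and 14 by at least 1.5-fold. CDC20, an activator of the anaphase-promoting complex, had 102, 268 and 243 FPKM. AURKB was 2.49-fold (2.24 to 2.76) and 2.75-fold (2.47 to 3.05) higher, and KIF20A 2.30-fold (2.07 to 2.56) and 3.35-fold (3.02 to 3.71). The S-phase list had medians of 0.91 (0.71 to 1.11) in sh1089-1 and 0.84 (0.58 to 0.92) in sh1089-2. The mitosis list had 0.96 (0.71 to 1.14) and 0.97 (0.73 to 1.25). All 4 medians lay at a percentile of 100.

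Interferon-induced genes were also higher in both. Of 15 measured members, 9 were at least 1.5-fold higher: IFIT1, IFIT2, IFIT3, IFI6, ISG15, OAS3, OASL, RIGI and RSAD2. ISG15, a ubiquitin-like protein, had 161, 386 and 384 FPKM. RSAD2, an antiviral enzyme, rested on 38, 152 and 191 reads and was 4.49-fold (3.13 to 6.59) and 6.43-fold (4.52 to 9.37) higher. IRF7, a transcription factor of the same response, was lower, with 7.61, 3.95 and 4.73 FPKM. The list medians were 0.69 (0.39 to 0.94) and 0.94 (0.53 to 1.22), both at a percentile of 100. The antigen presentation list, MHC class I genes and their processing partners, had no member of 12 past 1.5-fold in both. Its medians were −0.25 (−0.33 to −0.03) and −0.14 (−0.42 to 0.05), at percentiles of 0.48 and 8.67.

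The sterol synthesis list was higher in both, and further so in sh1089-2. INSIG1, a sterol-regulated feedback protein, had 16.1, 32.4 and 64.4 FPKM. FDFT1, the squalene synthase gene, was 1.62-fold (1.49 to 1.75) and 2.57-fold (2.38 to 2.76) higher. Of 14 measured members 11 were above shNC in both, 6 of them by at least 1.5-fold, while HMGCS1, SQLE and SC5D lay below it in sh1089-1 and above it in sh1089-2. The medians were 0.55 (−0.04 to 0.77) and 0.96 (0.55 to 1.23), both at a percentile of 100. In the fatty acid synthesis list, FASN, SREBF1 and FADS2 were higher in both among 9 measured members. SREBF1, the master regulator of lipid synthesis, had 16.4, 34.7 and 44.6 FPKM and lies in a stretch of chromosome 17 whose 50 genes had medians of 0.40 and 0.29. That list had medians of 0.23 (0.14 to 0.84), at a percentile of 94.8, and 0.79 (0.42 to 1.75), at 100, so it was not called. The Notch target list was called higher from only 3 measured genes. HES4 had 12, 18.6 and 24.1 FPKM, NRARP 1.13, 2.82 and 2.22, and HES1 2.41, 1.68 and 2.44. The medians were 0.59 and 0.59, at percentiles of 99.3 and 99.4. With no filter on low values they came to 0.08 and 0.11.

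Iron storage and antioxidant genes were lower in both hairpin libraries. FTL (chromosome 19, 48965301 to 48966878) had 18640 FPKM in shNC, 9245 in sh1089-1 and 6906 in sh1089-2, which was 1.62%, 0.805% and 0.601% of the reads. FTH1, the ferritin heavy chain, had 1948, 1117 and 790 FPKM, and HMOX1, heme oxygenase, 185, 97.4 and 63.6. SLC7A11, the cystine transporter, was 1.68-fold (1.48 to 1.91) and 1.91-fold (1.66 to 2.19) lower. All 10 measured members of the NRF2 list were below shNC in both, and these 4 by at least 1.5-fold. The medians were −0.53 (−0.92 to −0.19) and −0.68 (−1.43 to −0.31), both at a percentile of 0. Ferritin genes have many processed pseudogenes, which could share reads with them.

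Lysosomal genes were lower as well. SQSTM1, an autophagy receptor, had 337, 181 and 147 FPKM. CTSB and CTSD, cathepsins, were 2.04-fold (2.00 to 2.08) and 1.88-fold (1.70 to 2.07) lower in sh1089-1, and 1.68-fold (1.64 to 1.71) and 2.29-fold (2.05 to 2.55) lower in sh1089-2. Of 15 measured members, 14 were below shNC in both and 5 by at least 1.5-fold: LAMP2, CTSB, CTSD, CTSL and SQSTM1. The medians were −0.56 (−0.89 to −0.27) and −0.42 (−0.67 to −0.25), both at a percentile of 0.

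Inflammatory cytokine genes were lower in part. IL6 had 48.8, 15.2 and 20.5 FPKM. IL1B was 6.09-fold (3.69 to 10.6) and 5.34-fold (3.24 to 9.31) lower, on 123, 18 and 18 reads. CXCL8, a neutrophil chemokine, was 1.85-fold (1.55 to 2.21) and 3.11-fold (2.49 to 3.92) lower. IL1A and CXCL2 were the other members of the 5 that were lower, of 12 measured. None counted as higher in both, though by plain ratios IL11 and TNFAIP3 were, with 1.15, 4.98 and 2.14 and with 3.46, 5.56 and 5.74 FPKM. The medians were −0.32 (−1.46 to 0.14) and −0.48 (−1.47 to 0.22), at percentiles of 0.37 and 0.

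The p53 target, unfolded protein and histone lists were called lower from fewer members. In the p53 list 2 of 15 measured members counted as lower in both, GDF15 and BBC3, a BH3-only apoptosis gene, and 4 by plain ratios, with ZMAT3 and SESN1. CDKN1A, the cell cycle inhibitor p21, had 339, 206 and 263 FPKM, and MDM2 8.65, 8.25 and 8.44. Its medians were −0.26 (−0.55 to −0.06) and −0.36 (−0.57 to −0.03), at percentiles of 0.42 and 0.02. In the unfolded protein list 2 of 12 members counted as lower, DNAJB9 and SEL1L, and 3 by plain ratios, with HERPUD1. HSPA5, the main chaperone of the endoplasmic reticulum, had 599, 401 and 403 FPKM. Its medians were −0.28 (−0.58 to 0.08) and −0.26 (−0.64 to 0.09), at percentiles of 0.12 and 0.69. Of 9 measured histone genes, H1-2, H2BC5, H2BC21 and H4C8 were lower and H2AZ1, a replication-independent variant, was higher. H1-2 had 248, 111 and 97.1 FPKM, and H2AZ1 67.4, 130 and 120. Its medians were −0.67 (−1.16 to 0.36) and −0.33 (−1.34 to −0.23), at percentiles of 0 and 0.64. Most histone mRNAs lack a poly(A) tail, and mRNA was enriched here.

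**Figure D2:**
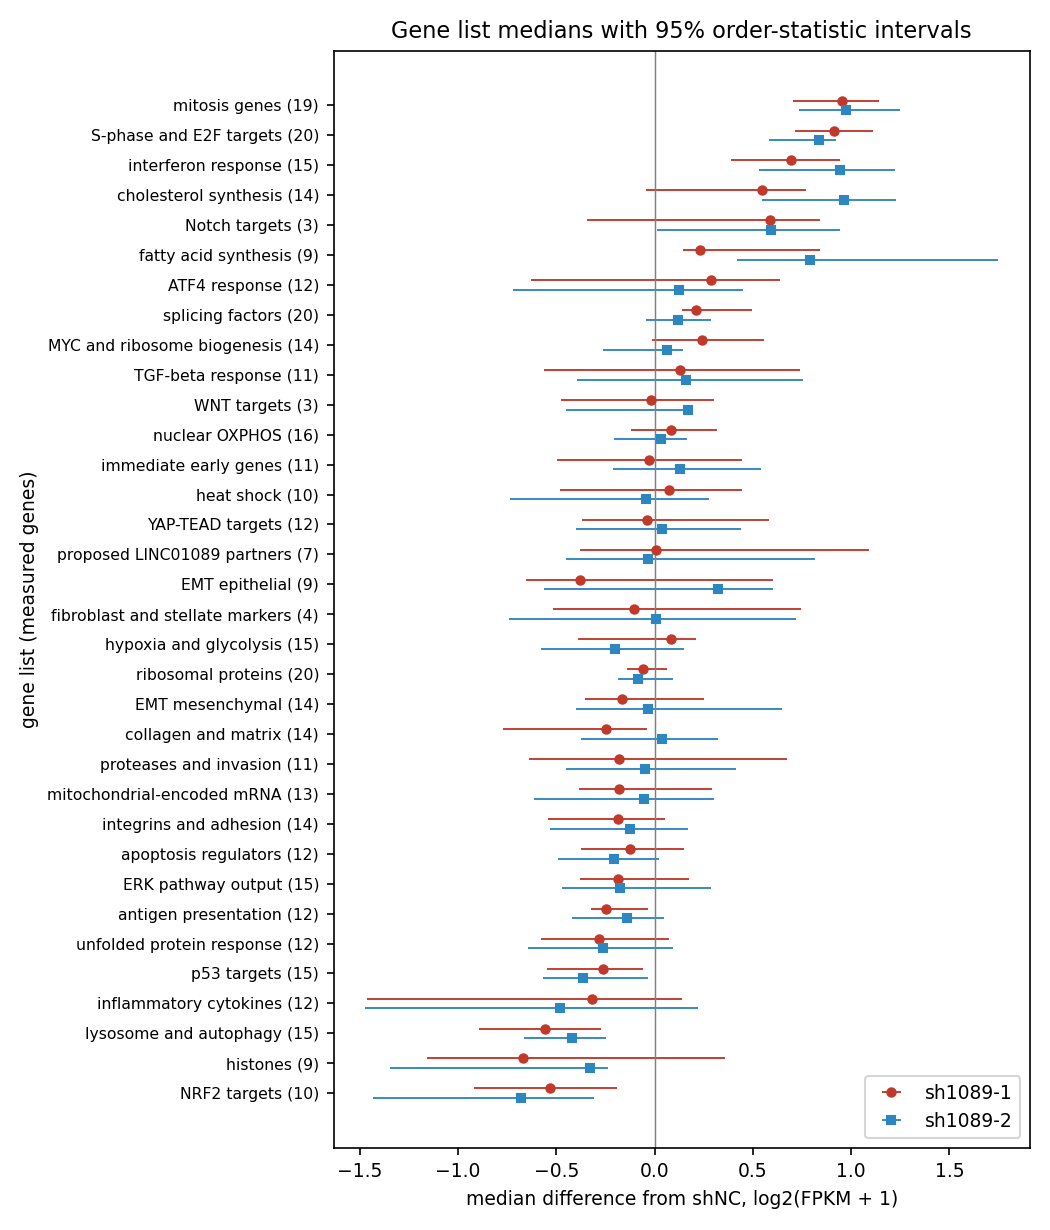
Median difference from shNC in log2(FPKM + 1) of each gene list with at least 3 measured genes. Values are given for sh1089-1 (circles) and sh1089-2 (squares), with 95% order-statistic intervals over the members. In the list of 7 partners the interval is the whole range. It is the whole range also in the lists of 3 and 4 genes, where it falls short of 95%. The S-phase and mitosis lists have medians from 0.84 to 0.97, and the NRF2 list −0.53 and −0.68.

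The proposed partners of LINC01089 were examined next, because earlier work on liver cancer ties it to HNRNPM, DIAPH3, IGF2BP3, E2F1 and ERK, ELK1 and SNAI1 signalling. Of 7 measured partners, DIAPH3 and E2F1 were higher in both and none was lower. DIAPH3 (chromosome 13, 59665583 to 60163987), a formin gene, was 2.38-fold (1.96 to 2.90) and 2.15-fold (1.76 to 2.65) higher, with 1.95, 4.63 and 4.2 FPKM. E2F1, a transcription factor of S-phase entry that is also in the S-phase list, had 7.85, 17.9 and 14.6 FPKM. HNRNPM, a splicing regulator, had 41.0, 64.3 and 59.3 FPKM, and IGF2BP3, an RNA-binding protein, 10.2, 7.61 and 7.20. MAPK3 had 18.7, 16.1 and 16.9 FPKM, and ELK1 20.5, 20.4 and 17.2. SNAI1, a repressor of epithelial genes, rested on 12, 7 and 11 reads, below the filter, and a difference was not detectable at this depth. The list medians were 0.01 and −0.03, at percentiles of 48.4 and 42.3. All these values are mRNA levels per gene. Isoforms, proteins and phosphorylation were not analysed here, so the values do not test the proposed ties.

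The ERK output list and the lists of the epithelial-mesenchymal transition were not called. In the ERK output list 1 of 15 members passed 1.5-fold in both, IER3, with 213, 133 and 123 FPKM. DUSP6 had 14.9, 10.9 and 8.71 FPKM, and FOSL1 191, 284 and 253. The medians were −0.18 and −0.17, at percentiles of 1.98 and 4.06. Of 14 mesenchymal members, CDH2 (N-cadherin) was higher, with 6.01, 11.3 and 12.3 FPKM, and S100A4 lower, with 14.4, 7.21 and 7.84. VIM had 922, 1171 and 1445 FPKM. Of the transcription factors, SNAI2 had 3.14, 2.29 and 1.65 FPKM, TWIST1 8.14, 9.88 and 9.46, ZEB1 2.11, 1.64 and 1.67, ZEB2 1.27, 0.871 and 1.04, TWIST2 1.30, 1.07 and 0.768, and FOXC2 3.32, 2.82 and 3.30. The mesenchymal medians were −0.17 and −0.03, at percentiles of 8.98 and 54.6. Of 9 epithelial members KRT18 and KRT19 were higher and CLDN1 lower. KRT18 had 739, 1244 and 1203 FPKM, and CLDN1, a tight junction gene, 19.2, 11.3 and 8.54. The epithelial medians lay on opposite sides of shNC, at −0.38 (−0.65 to 0.60) in sh1089-1 and 0.32 (−0.56 to 0.60) in sh1089-2, with percentiles of 0.335 and 99.6.

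Among the lists of the cell surface, the matrix and signalling, LAMC1 and LOX were lower in both of 14 collagen and matrix genes, with 126, 64.6 and 78.5 and 21.4, 10.7 and 11.7 FPKM. ITGA2 and ITGB3 were lower of 14 integrin and adhesion genes, and ITGB3 was 4.25-fold (2.77 to 6.76) and 3.03-fold (2.04 to 4.62) lower. The integrin medians were −0.19 and −0.12, at percentiles of 1.13 and 9.45. CTSL was lower of 11 protease genes, with medians of −0.18 and −0.05. In the TGF-beta list CCN2 and TGM2 were higher and TGFB2 lower of 11, with medians of 0.13 and 0.16. In the YAP-TEAD list CCN2 and F3 were higher and LATS2 lower of 12, with medians of −0.04 and 0.04. The apoptosis list had PMAIP1 higher of 12 (−0.12 and −0.21), and the ATF4 list had PHGDH higher and DDIT3, SLC7A11 and CEBPB lower of 12 (0.29 and 0.13). CEBPB had 111, 57.1 and 44.7 FPKM. In the hypoxia and glycolysis list ADM, NDRG1 and LDHA were lower of 15. LDHA had 578, 329 and 324 FPKM, and ADM and LDHA lie in the stretch of chromosome 11 named above.

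None of the remaining lists was called. The 20 listed ribosomal protein genes had medians of −0.06 and −0.08, at percentiles of 3.98 and 7.47, and none passed 1.5-fold. In a scan of 163 families by symbol, outside the fixed lists, the wider ribosomal sets were slightly lower. The 46 RPL genes had −0.06 and −0.15, at percentiles of 0.4 and 0 among 2000 random sets. The 37 RPS genes had −0.09 and −0.14, at 0.7 and 0.6. On the higher side lay the MCM family, at 100 and 100, and the PDE family, at 99.2 and 99.9. The MCM family shares MCM2, MCM3, MCM4, MCM5, MCM6 and MCM7 with the S-phase list, so it is not a separate result. No allowance was made for the number of families scanned. Mitochondrial mRNAs (13 genes) had −0.18 and −0.05, at percentiles of 0.535 and 19.6, with MT-ND6 lower, and 16 nuclear OXPHOS genes had 0.08 and 0.03. The 20 splicing factors had 0.21 and 0.12, 14 MYC and ribosome biogenesis genes 0.24 and 0.06, and 10 heat shock genes 0.08 and −0.04, with HSPA1A lower. In the immediate early list (11 genes) none counted as higher or lower in both (1 was higher by plain ratios, EGR1), nor did any of the 3 WNT targets. Few cell type markers were measured. Only 12 endothelial, 10 hepatocyte and 9 leukocyte markers were among the genes given FPKM values at all. ENG and ROBO4 were measured of 14 endothelial markers (0.33 and 0.17), SERPINA1 of 15 hepatocyte markers (0.28 and 0.66) and CD14 of 10 leukocyte markers (0.11 and −0.15). Of 4 measured fibroblast and stellate markers THY1 was higher, with 6.85, 12.2 and 11.9 FPKM, and by plain ratios LUM was lower, with 2.17, 1.22 and 0.896. The other members that passed 1.5-fold in both by plain ratios alone were RRM1, CDC45, POLA1, MAD2L1, IFI44, OAS2, MVK, DNAJB1 and TIMP3 (higher) and CLDN7, SMAD7, BIRC3 and GCLM (lower). In total 5 lists were called higher, 6 lower and 26 neither.

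Further members taken by the fixed rule mostly stayed within 1.5-fold of shNC in at least 1 hairpin and are given here as differences of log2(FPKM + 1) in sh1089-1 and sh1089-2. Of the MHC class I genes, which present peptides to T cells, the list had HLA-B (−0.39 and −0.15), HLA-C (−0.33 and −0.53) and HLA-E (−0.53 and −0.42). The immediate early transcription factors were JUN (0.44 and 0.55), EGR1 (0.88 and 0.37), ATF3 (0.37 and 0.54) and KLF4 (0.42 and 0.51). The ERK phosphatases were DUSP4 (−0.38 and −0.98) and DUSP5 (−0.51 and −0.47), and the apoptosis genes CASP8 (−0.42 and −0.22), BIRC3 (−0.49 and −0.50) and XIAP (−0.24 and −0.49). In the stress lists stood CHAC1 (1.06 and 0.42), HERPUD1 (−0.57 and −0.69), ZMAT3 (−0.46 and −0.70) and PFKFB3 (−0.39 and −0.58), and the chaperones DNAJB1 (0.58 and 0.80), HSPA8 (0.43 and 0.28) and HSPA1B (−0.48 and −0.73). The WNT targets were DKK1 (−0.47 and −0.45), ZNRF3 (−0.02 and 0.17) and BMP4 (0.30 and 0.17). FDPS, of the sterol pathway, had 0.77 and 1.21.

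Matrix and adhesion genes taken by the rule were COL5A2 (−0.52 and −0.25), COL6A1 (−0.77 and −0.37), ITGAV (−0.47 and −0.40) and ITGB1 (−0.54 and −0.53). The protease list gave PLAUR, the urokinase receptor (−0.50 and −0.41), and the inhibitors TIMP2 (−0.64 and −0.08) and TIMP3 (0.67 and 0.56). Of the stromal markers these were PDGFRB (−0.42 and −0.04), LUM (−0.52 and −0.74) and S100A6 (0.22 and 0.06), and of the junction and signalling lists CLDN7 (−0.65 and −0.56), BHLHE40 (0.26 and 0.75) and AJUBA (0.58 and 0.44). The nucleolar genes were BOP1 (0.60 and 0.23), NOP56 (0.43 and 0.21), NOP58 (0.56 and 0.05) and RRS1 (0.60 and 0.07), and the splicing factors PTBP1 (0.49 and 0.43), SRSF2 (0.66 and 0.42) and SRSF3 (0.72 and 0.32). Ribosomal protein genes were RPLP0 (0.23 and 0.16), RPS3 (0.27 and 0.13) and RPS24 (−0.15 and −0.27). For the respiratory chain the nuclear genes were NDUFA1 (0.42 and 0.08), UQCRB (−0.17 and −0.64), ATP5F1B (0.32 and 0.22) and NDUFV1 (0.46 and 0.27), and the mitochondrial ones MT-ND1 (−0.28 and −0.61), MT-ND4L (−0.43 and −0.75) and MT-ATP8 (0.48 and 0.49).

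**Figure D3:**
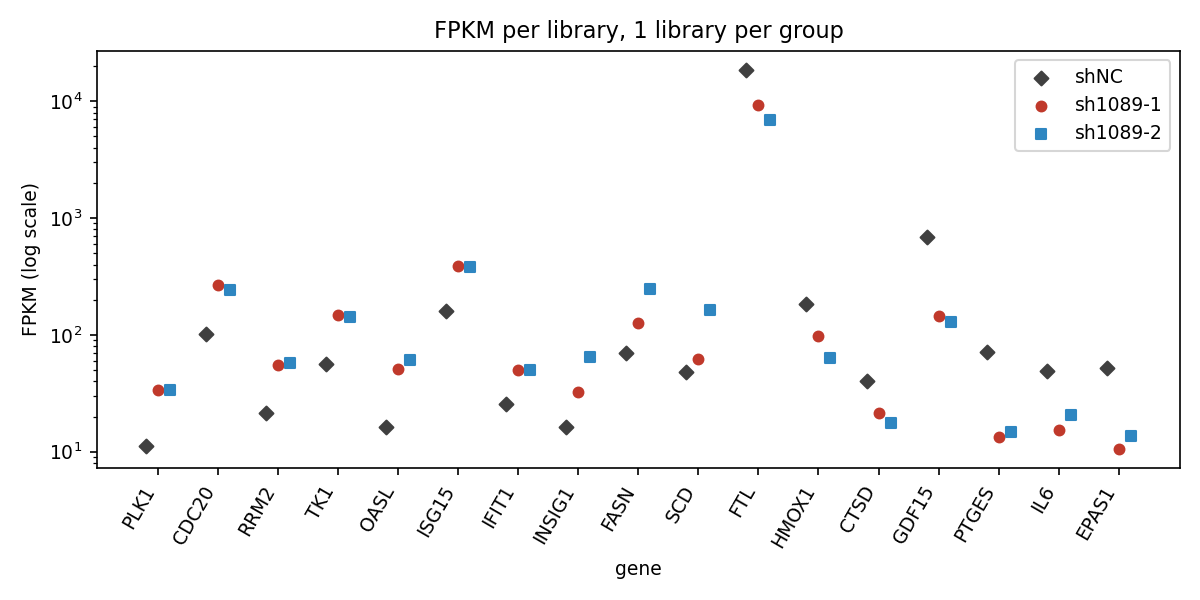
FPKM on a log scale (y axis) of 17 genes (x axis) in shNC (diamonds), sh1089-1 (circles) and sh1089-2 (squares), 1 library per group and so without error bars. PLK1 stands at 11.3 FPKM in shNC and at 33.8 and 34.0 in the hairpin libraries, while GDF15 stands at 687, 145 and 128.

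The last comparison set the hairpin libraries against each other. Lipid synthesis genes were higher in sh1089-2 than in sh1089-1, and nucleolar and splicing genes were lower. SCD was 2.66-fold (2.55 to 2.77), INSIG1 1.99-fold (1.85 to 2.14) and FASN 1.96-fold (1.91 to 2.00) higher in sh1089-2. The fatty acid list had a median of 0.48 (0.31 to 0.96) and the cholesterol list 0.41 (0.26 to 0.69), both at a percentile of 100. The collagen list, with 0.28 (0.11 to 0.40), and the protease list, with 0.24 (−0.12 to 0.49), lay at percentiles of 100 and 99.9. The interferon, antigen presentation, immediate early and Notch lists lay above the upper bound for a call with 0.15, 0.16, 0.13 and 0.36. Below the lower bound lay the MYC and ribosome biogenesis list with −0.23 (−0.42 to −0.14), splicing factors with −0.20 (−0.25 to −0.06), heat shock with −0.24 and hypoxia with −0.19. That makes 12 of 37 lists. Of single genes, 94 were at least 2-fold higher in sh1089-2 and 99 lower. Only 8 and 6 of the protein-coding genes with at least 100 reads were. TXNIP, a thioredoxin-binding protein, had 82.7 FPKM in shNC, 58.3 in sh1089-1 and 147 in sh1089-2, and PLAT 13.4, 31.2 and 66.6. KRT81 had 80.0, 86.3 and 40.4 FPKM, with the reservation made for KRT86.

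Genes that differed in 1 hairpin alone, by the fixed rule, were mostly short RNAs with few reads. RN7SL1, an RNA of the signal recognition particle, had 508 reads in shNC, 73 in sh1089-1 and 351 in sh1089-2, and its near copy RN7SL3 had 34, 2 and 23. The other lower genes in sh1089-1 were SNORD99, SNORD104 and MIR647, and in sh1089-2 ENSG00000274520, SNORA5C, MIR4786, ENSG00000258073 and a Y_RNA gene, all on 13 reads or fewer in each library. On the higher side MIR1290, RNU6-446P, MIR1276 and MIR5010 had 3 or 4 reads in sh1089-1 alone, and MIR631, MIR3128, RNA5SP264, ENSG00000255972 and MIR6813 had 1 to 5 in sh1089-2 alone. GAGE12J, a cancer-testis gene with near-identical copies, had 0, 164 and 0 reads. GAGE12G had 3, 5 and 161, while the 6 listed GAGE genes together had 48, 177 and 172 reads. EIF3C and its copy EIF3CL had 431, 160 and 530 reads together. How reads were shared among copies is not given in the sources used here.

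Short RNAs also filled most of the fixed ranking over all genes. Of its 12 higher genes 7 were short RNAs: MIR5587, MIR4746, RNU6-137P, MIR4258, RNU6-343P and 2 Y_RNA genes, with 0 reads in shNC and 2 to 14 in a hairpin library. Of its 12 lower genes 10 were: RNU6-237P, MIR4731, RNU7-57P, MIR378J, MIR616, MIR4730, SNORD81, MIR3192 and 2 Y_RNA genes, with 3 to 6 reads in shNC and 0 in the others. The remaining genes of that ranking, TENT5B, OASL, NRGN, ADAMTS6, PLK1, HSPA6 and GDF15, also lead the protein-coding one.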

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

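All results here were picked out because the hairpins lay on opposite sides of shNC. The size set for lists (a larger median of at least 0.1 in either hairpin, over at least 3 measured genes) was chosen after the medians were seen. None of these differences between the hairpins was tested, since each is 1 library against another.

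Short transcripts past 2-fold in opposite directions rested on 4 or 5 reads each over the 3 libraries. The differences of log2(FPKM + 1), sh1089-2 minus sh1089-1, were 3.30 for ENSG00000284651 (reads 1, 0 and 4 in shNC, sh1089-1 and sh1089-2), 2.80 for MIR3677 (1, 0 and 3), 2.44 for MIR4284 (1, 0 and 3), −2.72 for MIR4656 (1, 4 and 0) and −2.25 for MIRLET7I (1, 3 and 0). At such depth no difference was detectable.

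Lists whose medians lay on opposite sides of shNC differed as follows, sh1089-2 minus sh1089-1. The epithelial list differed by 0.70, from −0.38 to 0.32, while the median of its members' own differences was 0.09 (−0.05 to 0.32). The collagen and matrix list differed by 0.28, from −0.25 to 0.04. The hypoxia and glycolysis list differed by −0.29, from 0.08 to −0.20, and the WNT targets by 0.19, from −0.02 to 0.17 over 3 genes. The immediate early genes differed by 0.16, from −0.03 to 0.13, and the fibroblast and stellate markers by 0.11, from −0.10 to 0.01 over 4 genes. The median of the members' own differences was 0.28 for collagen and matrix, −0.19 for hypoxia and glycolysis and 0.13 for the immediate early genes. For the WNT targets it was only 0.02 (−0.13 to 0.19). For the fibroblast and stellate markers it had the opposite sign, −0.09 (−0.23 to 0.38).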

How the results depend on the processing

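With 1 library per group, no library could be left out. No paired analysis was possible because each group holds a single library. The level of LINC01089 and its rescaled values were not analysed here. The filter on protein-coding genes with at least 100 reads and the plain ratios were chosen after the data were seen, and the others before. Plain ratios raised the members counted in both hairpins from 102 to 122 of 426. Scaling to a median ratio of 1 moved no count past 1.5 times. Of 45 counts and correlations under the alternatives, 34 moved. Of 402 medians of gene lists, 397 stayed inside the interval of the main value. That interval is the spread over members and is wide in small lists. The Notch medians of 0.08 and 0.11 with no filter stayed inside it. Of 2408 values of named genes, 2336 moved by no more than the reach of their counting interval. None that was called or past 2-fold changed sign. A gene with 0 reads in a compared library has an unbounded reach and could not count as moved. The list medians outside their interval were those of the WNT targets (3 genes) and the S-phase list, both in sh1089-2. The WNT median came to 0.21 and 0.19 with pseudocounts of 0.1 and 0.5, 0.26 as TPM and 0.17 at a median ratio of 1. The S-phase median came to 0.95 as TPM. No scaling moved the median of all tested genes by more than 0.1. Percentiles of lists were not taken again.

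Genes at 2-fold or more numbered 323 (sh1089-1), 363 (sh1089-2), 164 (both) and 193 (between the hairpins), and r was 0.668. With a pseudocount of 0.1 they were 600, 607, 307 and 323, with r 0.600, and with 0.5 r was 0.646. No filter gave 549, 640, 279 and 471, with r 0.620, and a mean FPKM of at least 5 gave 139, 164, 83 and 40, with r 0.740. Rescaling to TPM gave 512 (sh1089-1), 257 (both, 59.9% of them higher against 49.4%) and 293 (between), with r 0.630. The pseudocount weighs less on the larger TPM values. A 1.5-fold threshold gave 1243, 1178, 657 and 535, and a 3-fold threshold 91, 119, 41 and 92. Protein-coding genes with at least 100 reads gave 150, 166, 84 and 14, with r 0.755. Beyond what their construction shows (fewer or more genes, a smaller threshold), the cause was not tested. The limma-trend fit that took the hairpins as 2 replicates rests on 1 control library and 1 residual degree of freedom, so its calls are not given. Its check on simulated values used a log2 change of 3. HSPA6, first in the protein-coding ranking of lower genes, had −2.66 and −2.68. The check therefore does not show what the fit recovers at the sizes seen here.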

Other observations

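The genes in the first 2 paragraphs were chosen after their values were seen. ID1, ID2 and ID3 encode inhibitors of basic helix-loop-helix transcription factors. ID1 had 101, 54.7 and 27.8 FPKM in shNC, sh1089-1 and sh1089-2, ID3 had 85.0, 37.0 and 20.2, and ID2 had 10.3, 7.64 and 3.57. HLA-DRA, an MHC class II gene, had 5.79, 14.8 and 27.2 FPKM, and CD74, the invariant chain, 6.82, 14.7 and 21.3.

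Further genes with like values in both hairpins were FOXM1, a transcription factor of the mitotic genes, with 18.2, 42.2 and 40.8 FPKM, and CDC25A, a phosphatase of cell cycle entry, with 2.68, 8.34 and 6.45. H2AX, a histone variant, had 51.1, 130 and 112 FPKM. On the lower side stood NCOA3, a nuclear receptor coactivator, with 12.5, 4.40 and 4.87 FPKM, CD55, an inhibitor of complement, with 16.3, 6.24 and 6.20, and KRT7, with 13.2, 5.75 and 3.89.

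In the tests below, those on the growth state, the MHC class I genes (both tests), the order of genes and the trend in regions were chosen after the results they bear on were seen. The cell cycle lists together had 39 measured genes, all above shNC in both hairpins, with medians of 0.92 and 0.87. A trend with GC content or gene length does not account for this: after its removal the smaller median was 0.90 (0.71 to 0.94). What stays open is the growth state of the control culture. The hairpin libraries, sh1089-2 minus sh1089-1, differed by −0.0591 (−0.144 to 0.0091) over these genes. That pools −0.15 (−0.19 to −0.06) for the S-phase list and 0.06 (−0.13 to 0.20) for the mitosis list. With 1 control library a slower shNC culture and a faster growth after knockdown cannot be told apart. As a hypothesis, loss of LINC01089 may go with more cycling cells in this line, which further control cultures would test.

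The interferon list kept a smaller median of 0.71 (0.44 to 1.00) after removal of the GC and length trend, which argues against that trend as its whole cause. In these 3 libraries the antigen presentation list did not rise as far as the interferon list. Both medians were known when that comparison was chosen, so it describes the values and does not decide the kind of response. The upper bound of the antigen presentation list lay below the lower bound of the interferon list in both hairpins (larger difference −0.421). The antigen presentation median was −0.25 (−0.33 to −0.03) in sh1089-1 and −0.14 (−0.42 to 0.05) in sh1089-2. These intervals are spreads over the members and not errors of a change between single libraries. They therefore cannot exclude a smaller rise after knockdown in either hairpin. A response to the virus or to hairpin RNA in general would also be present in shNC, and a difference between the lines in the strength of such a response was not tested.

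Neighbouring genes moved together along 3 chromosomes. The 1808 windows of 50 protein-coding genes overlap, so they are not separate observations. Of them, 19 had a median beyond 0.3 in a hairpin against shNC, up to 0.40, and none between the hairpins. A copy number difference between the stable lines would need such a shift. The regions were 8474205 to 19336715 on chromosome 17 (0.40 and 0.29, rest of the chromosome −0.02 and −0.03), 9384622 to 28108308 on chromosome 11 (−0.30 and −0.36, rest 0.09 and 0.05) and 32277910 to 47155378 on chromosome 2 (−0.27 and −0.33, rest −0.13 and −0.13). Chance order of the genes is argued against, since 0 of 100 shuffles reached that size (highest 0.260). After removal of the trend with GC content and gene length the medians stayed at 0.38 and 0.26 on chromosome 17 and at −0.26 and −0.31 on chromosome 11, so that trend stays open for chromosome 2 alone, where the smaller was 0.194 in size (−0.29 to −0.07 with its sign). A candidate explanation is a subclone in the control line that differs in copy number at these places, and DNA of the 3 lines was not analysed here.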
